A study of Mus musculus with 31 samples.

How the data were processed

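The samples were cultures of fibroblasts freshly isolated from the hearts of C57Bl/6 mice 8-12 weeks old. The cells were seeded in a flat layer (2D), in a three-dimensional arrangement (3D), or in 1 arrangement after another. A label such as 3D-2D was read as the order of the arrangements. The times spent in each arrangement, the material of the substrates and the number of mice per library are not given in the sources used here. RNA sequencing gave 29 libraries in 10 groups, with 3 libraries in every group but 3D-2D, which had 2. The samples also held 2 ATAC-seq libraries of chromatin, 1 from 2D and 1 from 3D, which came with no processed file and were not analysed here.

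The authors deposited 1 table of raw read counts per gene symbol, with 1 column per library and no normalization. It held 24421 genes and 5 summary lines of the counting program. The submitters' notes name TopHat, HTSeq, Bowtie and MACS2 with no version and no role, and the mm10 genome build. The annotation and the strand setting are not given in the sources used here. The table had 2 symbols that occurred on more than 1 line and 27 symbols that a spreadsheet had turned into dates. Of its 24419 different symbols, 23204 matched a current RefSeq symbol and 24286 matched a symbol or a synonym. The positions given below are those of RefSeq genes on mm10.

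The total of gene counts per library ranged from 8509987 to 29909400. Reads that were not uniquely aligned came to between 14.0% and 28.4% of the gene counts and summary counts of a library, reads outside any gene to between 4.84% and 10.0%, and reads in more than 1 gene to between 0.881% and 1.06%. The 10 most abundant genes of a library took between 7.63% and 15.7% of its gene counts. Counts without molecular identifiers are not independent molecules, so standard errors rest on the spread between libraries.

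Differences were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. All 29 libraries were fitted together with 1 mean per group. Genes were kept by filterByExpr, which left 14036 genes, and libraries were scaled by TMM factors, which ranged from 0.868 to 1.10. The quasi-likelihood test used robust dispersions, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. A gene was called changed at an adjusted p under 0.05. Fold changes are on the log2 scale, each with a standard error obtained from the fold change and the F statistic. Normalised counts are CPM, counts scaled by the effective library total, and a prior count of 2 was used for log2 CPM.

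The 8 comparisons were 3D with 2D, 3D-2D with 3D, 3D-2D with 2D, 3D-2D-3D with 3D-2D-2D, 3D-5days with 2D-5days, and the 3 pairs of substrates of 0.5, 8 and 64 kPa. A further contrast tested whether the difference between 3D and 2D at 5 days was the same as in the cultures with no stated time. The comparisons, the gene lists, the rule for named genes and the first set of alternative settings below were chosen before the data were examined. The rule named the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3 whose libraries did not overlap between groups, up to 4 called members of each list described, or its 2 most abundant members where none was called, and a panel of 19 fibroblast genes. Unnamed gene models, pseudogenes, Xist and Y-linked genes were left out of the rule, and the text gives part of the genes the rule names. Genes named outside the rule are marked as chosen after their values were seen.

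Of 35 gene lists, 31 had the 5 tested members needed for a test. Lymphocyte markers had 1 tested member, Schwann cell markers 4, erythroid markers 0 and mitochondrially encoded genes 0, and these were not tested. Lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. For each list the called members were counted by the adjustment over all genes and by an adjustment over the list alone. The replicate numbers pair libraries in the labels only. The numbers were taken as pairs where the deviations from the group means correlated at 0.1 or more across genes in every pair, which held for 3D with 2D, for the 5-day groups and for the 3 substrate comparisons. Another number at times correlated more. For 3D replicate 1 the same number gave 0.141 and another 0.165, for 3D-5days replicate 2 0.288 and 0.317. For 0.5 kPa replicate 2 with 64 kPa they were 0.191 and 0.300. For replicate 3 of 3D and of the substrates, and for 5-day replicate 1, the same number correlated most. The rule therefore does not establish that the numbers pair cultures.

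Alternative settings chosen in advance were RLE size factors, library totals alone, no filter, a filter of 1 CPM in at least 3 libraries, a fit of only the groups compared, the same fit with the replicate number as a block, DESeq2 1.42.0, leaving out each library in turn, the other list tests, and a 2-fold minimum for overlaps. Alternatives chosen after seeing the data kept the libraries of 1 kind of preparation alone, summed the most alike libraries of a group, added the block to DESeq2, estimated the correlation in list tests with the block, or contrasted culture times within an arrangement. The procedure was tested on simulated data made from these libraries. At a planted 2-fold change in 3 libraries, edgeR recovered 64.2% of the changed genes in the 3D and 2D libraries, 52.2% in the 5-day libraries and 50.7% in the 0.5 and 64 kPa libraries. With a shift of each gene also planted in the libraries numbered 3, it recovered 35.8% in the 3D and 2D libraries and 35.8% in the 0.5 and 64 kPa libraries. With only the groups compared it recovered 0% in both, with the block 19.4% and 16.4%, and DESeq2 recovered 56.7% and 46.3%. In the simulations without the shift, false calls made up 1.74% to 8.89% of the calls of edgeR. With the shift, 12 of 116 calls of DESeq2 were false in the 3D and 2D libraries and 6 of 104 in the 0.5 and 64 kPa libraries. A planted list was recovered in each of the 5 simulated comparisons, with 0 other lists called. The simulated genes varied independently of each other, so this could not show false list calls that correlation between genes would cause.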

Results

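Expression was measured by RNA sequencing in cardiac fibroblasts, the matrix-producing cells of the heart, held in different spatial arrangements. There were 3 libraries each of 2D, 3D, 3D-2D-3D, 3D-2D-2D, 2D-5days, 3D-5days, 2D-0.5kPa, 2D-8kPa and 2D-64kPa cultures, and 2 of 3D-2D cultures. The total of gene counts per library was 12289359 to 28330718 in 2D, 18777061 to 26324009 in 3D and 20923257 to 24134346 in 3D-2D. It was 21390619 to 29909400 in 3D-2D-3D, 9318778 to 13679179 in 3D-2D-2D, 8509987 to 9588559 in 2D-5days and 9060433 to 11280045 in 3D-5days. The substrate groups had 9053061 to 14345895 at 0.5 kPa, 11564574 to 16227198 at 8 kPa and 9845569 to 14282655 at 64 kPa. The libraries were not all alike in origin. Libraries 1 and 2 of 2D, 3D, 3D-2D and 3D-2D-3D held reads of Xist and almost none of Y-linked genes. Libraries 3 of 2D, 3D and 3D-2D-3D and all 3D-2D-2D and 5-day libraries held both, and the substrate libraries held Y-linked reads and only 1 to 7 reads of Xist. Within most groups the libraries were not equally alike. The SD over genes of the log2 CPM difference was 0.343 between 2D libraries 1 and 2, and 0.760 and 0.750 between these and library 3. In 3D the same values were 0.280, 1.06 and 0.966. Libraries 1 and 2 of 3D-2D-3D and of each substrate, and 2 and 3 at 5 days, were likewise the most alike. Nothing in the sources used here says whether the libraries of a group came from separate cultures. The p-values, standard errors and agreement of pairs then measure only the spread between these libraries, which may be technical. With the most alike libraries summed, a setting chosen after seeing the data, 5505 genes were called between 3D and 2D, 6464 between 3D-2D and 3D, 220 between 3D-2D and 2D, 4109 between 3D-2D-3D and 3D-2D-2D, and 2512 at 5 days. Values below are log2 fold changes ± standard error from edgeR, with n = 3 libraries per group except n = 2 for 3D-2D, and adjusted p-values are from its quasi-likelihood test with Benjamini-Hochberg adjustment.

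**Figure D1:**
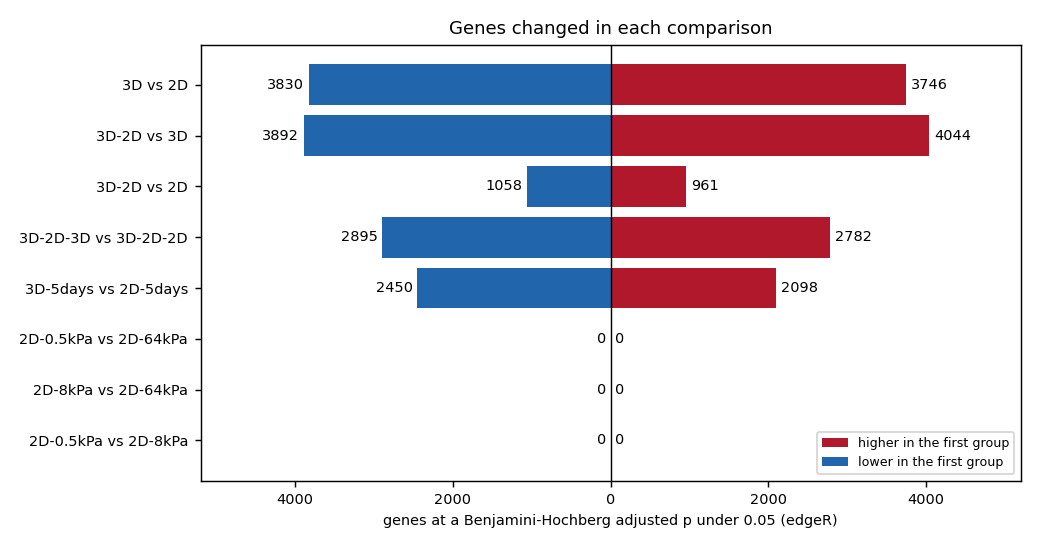
Genes called higher (red, to the right) or lower (blue, to the left) in the first group of each of 8 comparisons, at an adjusted p under 0.05 by edgeR. The 5 comparisons that involve a change of arrangement called between 2019 and 7936 genes, and the 3 comparisons of substrates called 0.

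The first comparison asked how cells held in 3D differed from cells in a 2D layer. The contractile and stress-fibre genes of the activated fibroblast were far lower in 3D. Acta2, which encodes smooth muscle actin and lies on mm10 chromosome 19 from 34240336 to 34255585, fell from a mean of 3066 CPM (SD 995, n = 3) to 53.5 CPM (SD 6.11, n = 3), a log2 change of -5.84 ± 0.47 (adjusted p = 2.64e-09). Tagln (transgelin) changed by -5.69 ± 0.38, Myl9 (myosin light chain) by -5.06 ± 0.42 and Ankrd1, a nuclear protein induced by stretch, by -6.67 ± 0.56 (adjusted p = 4.60e-09). Mmp2 (gelatinase A) was higher in 3D at 3.87 ± 0.26, with 3703 CPM in 3D and 254 CPM in 2D. In all, 7576 of 14036 genes changed, 3746 higher and 3830 lower in 3D, and 3444 of them by at least 2-fold.

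Other large falls were in Cemip, which takes part in hyaluronan breakdown (-5.68 ± 0.32), Anln, a cytokinesis protein (-5.23 ± 0.44) and the amino acid transporter Slc1a6 (-5.08 ± 0.44). The largest rises were in Agt, the angiotensin precursor (5.47 ± 0.51, adjusted p = 1.71e-08), Dkk3 (5.17 ± 0.38), the elongation factor gene Eef1a2 (4.88 ± 0.58) and Gem, a small GTPase (4.80 ± 0.18, adjusted p = 2.00e-14). Next came Igfbp5, a binding protein of insulin-like growth factors (4.70 ± 0.45, to 2325 CPM), Mmp11 (4.52 ± 0.18), Bmf, a pro-apoptotic protein (4.48 ± 0.44), and Fbln7 (4.29 ± 0.32). Without 2D replicate 3, Agt was at 6.16 and Dkk3 at 6.05. Of the 26 tested contractile genes 25 fell and 0 rose, the same counts when adjusted over the list alone, with a median of -2.14 (camera adjusted p = 5.13e-27). Targets of the mechanosensitive co-activators YAP and TAZ fell in 12 of 22 cases and rose in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.000127). Ctgf (-3.77 ± 0.33), Amotl2 (-3.82 ± 0.18) and Crim1 (-3.20 ± 0.16) were among the targets that fell, and Cyr61 (-2.44 ± 0.55) was no longer called with the replicate block (-3.06). Of 28 genes of integrins and focal adhesions, 16 fell and 3 rose (17 and 4 adjusted over the list alone, camera adjusted p = 0.00226). Parva fell (-1.79 ± 0.13), as did Cav1 (-4.35 ± 0.60, and -4.94 without 3D replicate 3). With an estimated correlation between genes, the contractile, YAP and TAZ, integrin and lysosome lists kept their calls, at adjusted p-values of 0.0222, 0.0288, 0.0425 and 0.0288.

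Cells in 3D had low levels of proliferation and cholesterol synthesis genes. Of 40 cell cycle genes 39 fell and 0 rose, the same when adjusted over the list alone, with a median of -3.50 (camera adjusted p = 9.43e-25, and 0.107 with an estimated correlation). Cenpf (-4.77 ± 0.54), Cdc20 (-4.71 ± 0.32), Ccnb1 (cyclin B1, -4.41 ± 0.38) and the proliferation marker Mki67 (-3.98 ± 0.75, and -4.62 without 3D replicate 1) were among them. Of 24 cholesterol synthesis genes 20 fell and 0 rose (21 and 1 adjusted over the list alone, camera adjusted p = 1.19e-06, and 0.466 with an estimated correlation). Idi1 (-3.13 ± 0.42) was among them. The cholesterol list was not called in replicate 3 alone (adjusted p = 0.0848), with 1 library per group, assumed to vary like the other groups. Of 30 ribosomal protein genes 29 fell by small amounts and 0 rose, the same adjusted over the list alone (camera adjusted p = 1.19e-06, and 0.556 with an estimated correlation). Rpl18 (-0.77 ± 0.11) and Rpl8 (-0.76 ± 0.11) were among them. Genes of the unfolded protein and integrated stress responses fell in 16 of 30 cases and rose in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.00237, and 0.575 with an estimated correlation), led by Psat1, an enzyme of serine synthesis (-3.43 ± 0.19).

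Lysosomal genes rose in 3D. Of 32 tested, 28 rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 1.77e-18). The saposin precursor Psap (2.39 ± 0.36) and the cathepsins Ctsb (2.33 ± 0.36) and Ctsd (2.06 ± 0.30) rose. Each of the 3 lost its call with the replicate block, at 2.21, 2.18 and 1.98. Markers of macrophages, which are rich in lysosomes, moved in opposite directions in replicates 1 and 2 and in replicate 3. They had mean log2 CPM values of 6.94 and 6.51 in 3D replicates 1 and 2, of 2.16 in 3D replicate 3 and of 4.57 to 4.73 in 2D. Of 21 macrophage markers 7 rose and 0 fell by the adjustment over all genes, 0 of either were called when adjusted over the list alone, and the list was not called (camera adjusted p = 0.331). Metalloproteinases and other matrix proteases rose in 18 of 33 cases and fell in 7 (19 and 7 adjusted over the list alone, camera adjusted p = 0.00480, 0.401 with an estimated correlation and 0.0658 with the block). Mmp11 and Mmp2 rose, as above, and Mmp17, a membrane-bound member, fell (-3.41 ± 0.42). Resting fibroblast markers rose in 13 of 27 cases and fell in 5, with the same counts adjusted over the list alone (camera adjusted p = 0.0211, and 0.466 with an estimated correlation). Pi16 (4.25 ± 0.77), Smoc2 (3.10 ± 0.39) and Cygb (cytoglobin, 3.09 ± 0.37) were among them. In replicate 3 alone neither list was called (adjusted p = 0.306 for proteases and 0.228 for resting markers), and Pi16 missed its call at 2.04. Of 13 adipogenic genes 10 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.00535, 0.0815 with an estimated correlation and 0.0528 with the block), led by the lipid droplet gene Plin4 (3.88 ± 0.48, and 4.73 without 2D replicate 3). The median of the adipogenic list was 3.35 in replicates 1 and 2 and 0.34 in replicate 3.

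Structural matrix genes did not move as a set. Col1a1, the main chain of collagen I, was at -0.06 ± 0.33 (12215 CPM in 3D and 12729.7 in 2D), and Col3a1 at 0.22 ± 0.61, neither called. Of 20 collagen chains 8 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.623), and of 38 matrix glycoproteins and proteoglycans 12 rose and 10 fell (12 and 10 adjusted over the list alone, camera adjusted p = 0.802). Genes of collagen processing and crosslinking fell in 12 of 20 cases and rose in 3 (12 and 4 adjusted over the list alone, camera adjusted p = 0.00517, 0.575 with an estimated correlation and 0.0528 with the block). Lox (lysyl oxidase, -3.26 ± 0.46, and -4.13 without 3D replicate 3), P4ha3, a prolyl hydroxylase (-2.34 ± 0.17), and Loxl3 (-2.17 ± 0.21) were lower in 3D. Secreted growth factors fell in 15 of 34 cases and rose in 6 (16 and 6 adjusted over the list alone, camera adjusted p = 0.0211, 0.0815 with an estimated correlation and 0.157 with the block). Bmp4 (-3.67 ± 0.35), Gdf6 (-3.48 ± 0.16) and Bdnf (-3.38 ± 0.18) were among them. Epicardial and mesothelial markers fell in 8 of 13 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.0332, 0.107 with an estimated correlation and 0.0639 without 3D replicate 1). Krt19 (-2.79 ± 0.62) was among them. The cytokine gene Il6 was at -1.89 ± 0.85 (adjusted p = 0.0633), Ccl2 at -0.15 ± 0.71, Mmp3 (stromelysin) at 1.74 ± 0.94 and Tcf21, a transcription factor of resting fibroblasts, at 0.57 ± 0.32, none called.

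A few panel genes rested on single libraries or sets of libraries. Timp1, an inhibitor of metalloproteinases, was called lower (-1.29 ± 0.41) and was at -0.56 without 2D replicate 3, which ended the call. Postn (periostin, 0.89 ± 0.29) lost its call without 2D replicate 3 (0.59) or 3D replicate 2 (0.71). Fn1 (fibronectin, -0.66 ± 0.19) lost it without 3D replicate 1 (-0.49) or 2 (-0.49), and in replicate 3 alone it turned to 0.19, not called. The calls of Pdgfra (0.85 ± 0.20) and Igf1 (2.19 ± 0.53) ended with the replicate block, at 0.94 and 1.96. Replicates 1 and 2 alone called 7098 genes and replicate 3 alone 5329, the latter with 1 library per group and the spread taken from the other groups, so the counts do not compare like with like. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.59, and 6184 of the 7098 genes (87.1%) had the same sign in replicate 3. With the replicate block 5307 genes were called. Scaling by library totals moved the median of all genes to 0.16 and gave 4541 genes higher and 3130 lower.

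**Figure D2:**
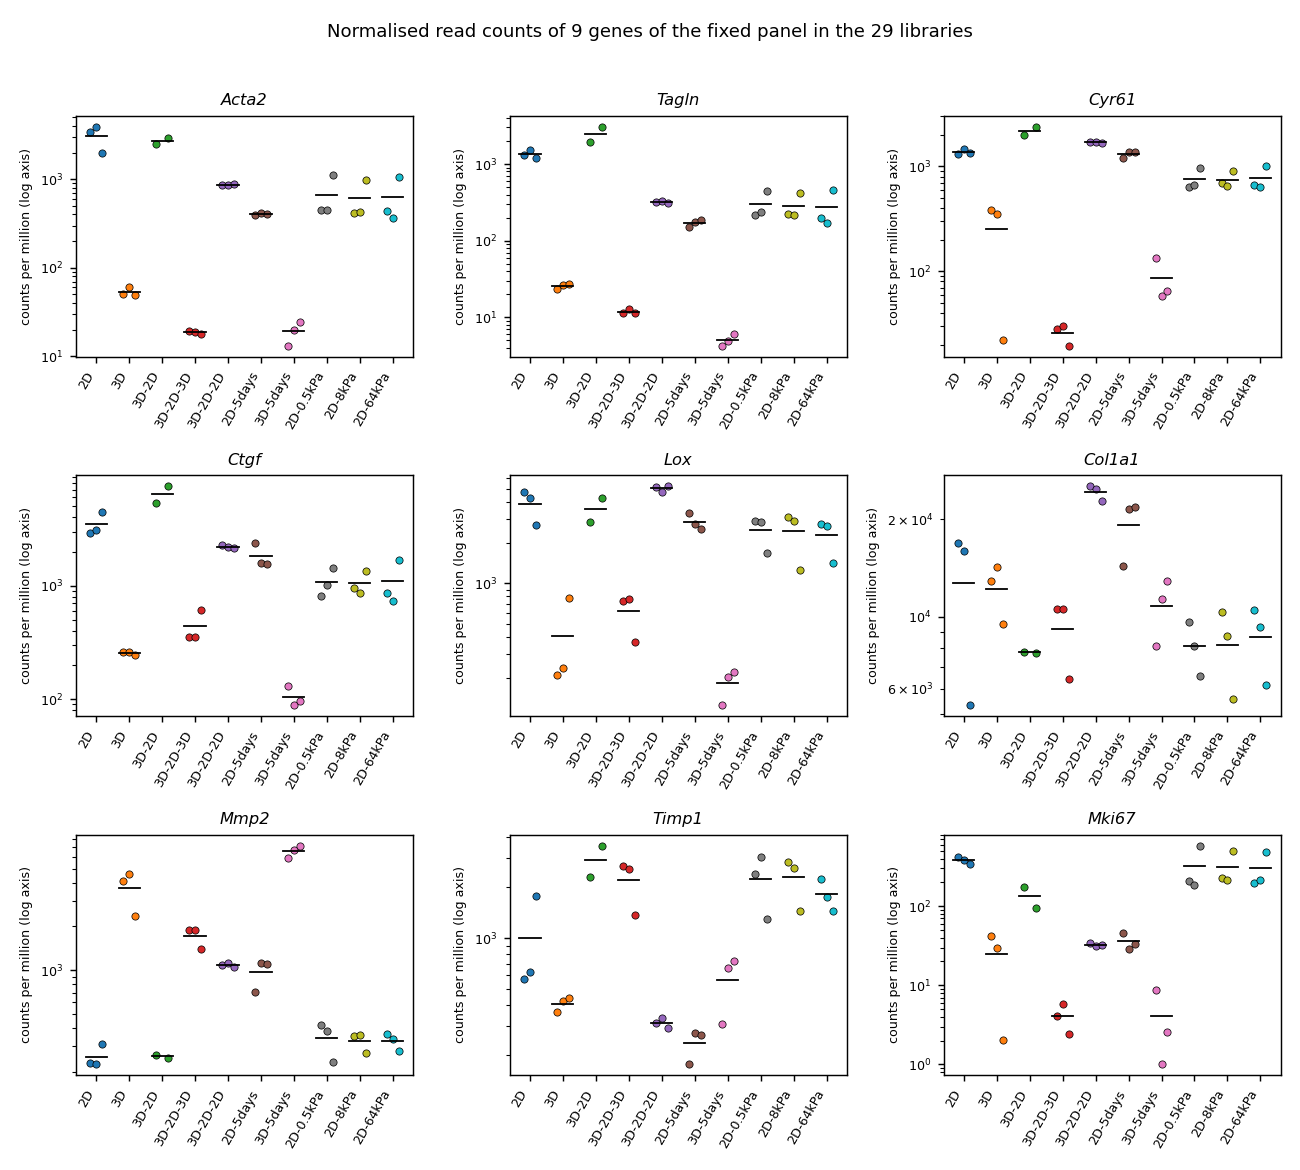
Normalised read counts (CPM, log axis) of 9 genes of the panel in the 29 libraries, with 1 point per library and a bar at the group mean. Acta2 had a mean of 3066 CPM in 2D, 53.5 in 3D, 2681 in 3D-2D, 18.6 in 3D-2D-3D and 871 in 3D-2D-2D.

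The second comparison asked what changed when cells from 3D were moved to 2D. Acta2 rose by 5.65 ± 0.48, from 53.5 CPM (SD 6.11, n = 3) to 2681 CPM (SD 290.5, n = 2, adjusted p = 5.13e-09), Tagln by 6.59 ± 0.40 and Ankrd1 by 8.22 ± 0.61. Mmp11 (-4.90 ± 0.22), Mmp2 (-3.86 ± 0.30), Gem (-6.03 ± 0.23, adjusted p = 3.47e-14) and Dkk3 (-5.64 ± 0.47), which were high in 3D, were lower after the move. In all, 7936 of 14036 genes changed, 4044 higher and 3892 lower in 3D-2D, and 4130 of them by at least 2-fold.

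Other genes with large rises were Sprr1a, a cornified envelope protein induced by stress (6.08 ± 0.90), the integrin ligand Npnt (5.68 ± 0.44) and Asb5 (5.61 ± 0.39). Besides Gem and Dkk3, given above, the largest falls were in Lum, the matrix proteoglycan lumican (-6.78 ± 1.58), Pdlim3 (-6.77 ± 1.43), Heyl, a target of Notch signalling (-6.56 ± 0.80), Bmf (-6.44 ± 0.59), the protease Htra3 (-6.06 ± 0.82) and Tgfbi, a matrix protein induced by TGF-beta (-5.63 ± 0.34). Against 3D replicate 3 alone Lum was at -2.87 and was not called. Leaving out 1 library moved Sprr1a to 6.78 and Itga3, named below, to 3.18 (without 3D replicate 3), Bmf to -7.03 (without 3D-2D replicate 1) and Lum to -7.45 (without 3D-2D replicate 2). Contractile genes rose in 23 of 26 cases and fell in 0 (24 and 0 adjusted over the list alone), with a median of 2.45 (camera adjusted p = 1.27e-26). YAP and TAZ targets rose in 11 of 22 cases and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.000108). Ctgf was at 4.65 ± 0.35, Amotl2 at 4.21 ± 0.19 and Cyr61 at 3.10 ± 0.60. Integrin and focal adhesion genes rose in 14 of 28 cases and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.00108). Itga3 (2.57 ± 0.33) and Cav1 (4.02 ± 0.61) were among them. These 3 lists kept their calls with an estimated correlation, at adjusted p-values of 0.0246, 0.0408 and 0.0478, and the other lists named here lost theirs.

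Cell cycle genes rose in 39 of 40 cases and fell in 0, the same adjusted over the list alone (camera adjusted p = 9.51e-12, and 0.339 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 3.45 ± 0.59 and Cdc20 at 3.14 ± 0.32. Mki67 rose by 2.46 ± 0.75, or 3.10 without 3D replicate 1, and its call ended without 3D-2D replicate 1 (1.98). Cholesterol synthesis genes rose in 17 of 24 cases and fell in 0, the same adjusted over the list alone (camera adjusted p = 0.000444, and 0.642 with an estimated correlation). All 30 ribosomal protein genes rose, and all did when adjusted over the list alone (camera adjusted p = 2.09e-07, and 0.518 with an estimated correlation), by amounts such as 0.97 ± 0.12 for Rpl18. Lysosomal genes fell in 27 of 32 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 1.96e-11, and 0.120 with an estimated correlation). Ctsb (-2.58 ± 0.43), Psap (-2.21 ± 0.42) and the cholesterol transporter Npc1 (-1.81 ± 0.18) were among them. Psap missed its call against 3D replicate 3 alone (-0.74). The macrophage markers, at a mean log2 CPM of 3.91 and 3.56 in 3D-2D, fell in 14 of 21 cases and rose in 0 (17 and 0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0677).

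Matrix proteases fell in 18 of 33 cases and rose in 3 (20 and 4 adjusted over the list alone, camera adjusted p = 0.000326, and 0.206 with an estimated correlation). Resting fibroblast markers fell in 15 of 27 cases and rose in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 0.000444, and 0.201 with an estimated correlation). The ferritin receptor Scara5 (-5.62 ± 0.56) and the matrix protein Dpt (-4.49 ± 0.81) were among them. Interferon response genes fell in 17 of 30 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.00808, 0.642 with an estimated correlation and 0.0849 against 3D replicate 3 alone). The immunoproteasome gene Psmb9 was lower (-3.16 ± 0.69), and it was not called against 3D replicate 3 alone (-1.79). Adipogenic genes fell in 9 of 13 cases and rose in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.0110, and 0.168 with an estimated correlation). Plin4 was at -5.10 ± 0.62. Without 3D-2D replicate 1, Plin4 was at -5.74 and Scara5 at -6.42. Genes of oxidative phosphorylation rose in 18 of 33 cases and fell in 0 (17 and 0 adjusted over the list alone, camera adjusted p = 0.0491, and 0.642 with an estimated correlation). Atp5b (0.66 ± 0.10) was among them. The call ended with library totals (adjusted p = 0.143), without 3D replicate 3 (0.0633) and without 3D-2D replicate 1 (0.0610) or 2 (0.0604).

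In the panel, Timp1 rose (2.85 ± 0.45), and Igf1 (-3.11 ± 0.64) and Tcf21 (-1.62 ± 0.37) fell. Col1a1 was at -0.65 ± 0.37 and Fn1 at 0.25 ± 0.21, neither called. Col3a1 (-1.95 ± 0.74, adjusted p = 0.0295) lost its call without 3D replicate 1 (-1.83) or 2 (-1.71) and without 3D-2D replicate 1 (-1.73) or 2 (-2.19). With 2 libraries in 3D-2D, leaving either out leaves 1 library, assumed to vary like the other groups, and the count was lowest, 5761 genes, without 3D-2D replicate 2. Scaling by library totals moved the median of all genes to -0.16 and gave 3250 genes higher and 4641 lower.

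The third comparison asked how far cells that had passed through 3D differed from cells kept in 2D. Of 26 contractile genes 4 were higher and 1 lower in 3D-2D, and the list was not called (camera adjusted p = 0.0812). Acta2 was at -0.19 ± 0.43, Lox at -0.12 ± 0.48, Postn at -0.11 ± 0.32 and Mmp2 at 0.01 ± 0.26 in 3D-2D relative to 2D, with 2 and 3 libraries, and none of these was called. Tagln (0.90 ± 0.34, adjusted p = 0.0766), Ctgf (0.88 ± 0.32, adjusted p = 0.0697) and Col1a1 (-0.71 ± 0.37) were not called either. In all, 2019 of 14036 genes changed, 961 higher and 1058 lower in 3D-2D, and 751 of them by at least 2-fold, but the count fell to 171 genes without 3D-2D replicate 2.

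Among the named genes that were called, 12 of 33 kept their calls without 3D-2D replicate 2. They included Nqo1, a quinone reductase (2.24 ± 0.42), Gsta4, a glutathione transferase (2.06 ± 0.41, and 2.66 without 2D replicate 3), the orphan nuclear receptor Nr4a2 (2.64 ± 0.40) and Mgll (monoglyceride lipase, 2.48 ± 0.33), which were higher in 3D-2D. Those lower in 3D-2D included Gucy1a3, a subunit of soluble guanylate cyclase (-3.98 ± 0.68), Afap1l2 (-3.37 ± 0.54), the aggrecanase Adamts5 (-2.77 ± 0.40), Adamts1 (-1.86 ± 0.30), the transporter Abca8a (-2.38 ± 0.34), the transcription factor Tcf4 (-0.78 ± 0.10), Gbp2, a GTPase induced by interferon (-2.01 ± 0.35), and the receptor gene Tek (-2.22 ± 0.39). The other 21 ended. Without that library, Ptgs2 (cyclooxygenase, 3.11 ± 0.67) was at 2.66, Sema7a (3.54 ± 0.70) at 2.95 and Timp1 (1.55 ± 0.44) at 1.21. Without 2D replicate 3, Sema7a was at 5.08 and Timp1 at 2.28. Among the falls that ended were the elastin gene Eln (-4.22 ± 0.89) at -4.67 and Kif26b (-4.29 ± 0.78) at -4.16. Leaving out 3D-2D replicate 1 ended 6 of the 33 calls, leaving out 2D replicate 1 or 2 ended 4, and leaving out 2D replicate 3 ended 0.

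No list held its call here with an estimated correlation (adjusted p = 0.644 for each list given as called in this paragraph). Cell cycle genes were lower in 14 of 40 cases (20 adjusted over the list alone) and higher in 0, with a median of -0.99 (camera adjusted p = 3.24e-09). Ccnb2 (cyclin B2, -1.91 ± 0.32) and Kif20a (-1.89 ± 0.32) lost their calls without 3D-2D replicate 2, at -1.52 and -1.56. Matrix glycoproteins were lower in 9 of 38 cases and higher in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.00291). Matrix proteases were lower in 6 of 33 cases and higher in 0 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0140), and resting fibroblast markers were lower in 5 of 27 cases and higher in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 0.000639). Oxidative stress genes were higher in 6 of 23 cases and lower in 0 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0306, and 0.0788 without 2D replicate 3). Genes of the unfolded protein and integrated stress responses were lower in 6 of 30 cases and higher in 0 (11 and 0 adjusted over the list alone, camera adjusted p = 0.00155). Oxidative phosphorylation genes were higher in 6 of 33 cases and lower in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 0.00110, and 0.192 with the block). Interferon genes were lower in 4 of 30 cases and higher in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 0.000838). Endothelial markers were lower in 1 of 19 cases and higher in 0 (1 and 0 adjusted over the list alone, camera adjusted p = 0.0170). Both calls ended without 2D replicate 3, at adjusted p-values of 0.795 and 0.129. The macrophage list was not called (adjusted p = 0.0599), and Lyz2 (lysozyme) was at -0.69 ± 0.93, not called.

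The fourth comparison asked what a return to 3D changed, with cells held in 2D for both later phases as the reference. Cells returned to 3D again had little contractile expression. Acta2 changed by -5.55 ± 0.47, from 871 to 18.6 CPM (adjusted p = 8.15e-09), Tagln by -4.77 ± 0.36 and Myl9 by -5.14 ± 0.43. Unlike in the first comparison, the fibrillar collagens were called lower, with Col1a1 at -1.40 ± 0.33 (9202 against 24281 CPM) and Col3a1 at -3.05 ± 0.66, a difference between comparisons that was not itself tested. Spp1 (osteopontin) reached 9401 CPM against 117 (6.33 ± 0.96, adjusted p = 1.87e-05). In all, 5677 of 14036 genes changed, 2782 higher and 2895 lower in 3D-2D-3D, and 2556 of them by at least 2-fold.

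The other large rises were in Ptgs2 (5.67 ± 0.75), the lipase inhibitor Angptl4 (5.61 ± 0.93), the chromatin protein Hmga2 (5.53 ± 1.15, and 4.95 without 3D-2D-3D replicate 3), Ngef (5.46 ± 0.76), the potassium channel Kcnh2 (5.41 ± 0.76) and Mmd (5.04 ± 0.64). Nptx1 (neuronal pentraxin) rose from 0.127 to 524 CPM in edgeR (11.90 ± 2.01, and 10.59 without 3D-2D-3D replicate 3), with 4 reads in all in 3D-2D-2D, and was not called by DESeq2. The large falls were in Cemip (-8.05 ± 0.36, from 5301 CPM), Sfrp2, a Wnt antagonist (-6.72 ± 0.65), Bmp4 (-6.33 ± 0.37), Wisp2 (-6.31 ± 0.88) and Sorbs2 (-6.14 ± 0.41), and in Figf, a growth factor of lymphatic vessels (-6.07 ± 0.45), Cyr61 (-6.04 ± 0.65) and Scel (-5.81 ± 0.47). Cholesterol synthesis genes fell in 23 of 24 cases and rose in 0, the same adjusted over the list alone, with a median of -3.14 (camera adjusted p = 3.37e-30, and 0.0664 with an estimated correlation). Idi1 (-4.11 ± 0.44), Fdps (-3.73 ± 0.39) and Lss (-3.68 ± 0.29) were among them. Contractile genes fell in 22 of 26 cases and rose in 1 (23 and 1 adjusted over the list alone, camera adjusted p = 9.22e-16, and 0.0664 with an estimated correlation). YAP and TAZ targets fell in 11 of 22 cases and rose in 4, the same adjusted over the list alone (camera adjusted p = 0.000535, and 0.0664 with an estimated correlation). Amotl2 was at -5.06 ± 0.19, Ankrd1 at -3.42 ± 0.48 and Ctgf at -2.33 ± 0.31. No list held its call with an estimated correlation in this comparison.

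Genes that build and process collagen fell. Of 20 collagen chains 13 fell and 3 rose (13 and 4 adjusted over the list alone, camera adjusted p = 0.000967, and 0.325 with an estimated correlation). Col11a1 was at -2.89 ± 0.52 and Col15a1, of basement membranes, at 3.39 ± 0.29. Of 20 collagen processing genes 15 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 3.36e-09, and 0.219 with an estimated correlation). Lox (-3.01 ± 0.46), Plod2 (lysyl hydroxylase, -2.54 ± 0.33) and P4ha3 (-2.21 ± 0.17) were among them. Matrix glycoproteins fell in 22 of 38 cases and rose in 6 (22 and 7 adjusted over the list alone, camera adjusted p = 0.0121, 0.508 with an estimated correlation and 0.0728 without 3D-2D-3D replicate 3). Eln (-4.57 ± 0.73, and -5.25 without 3D-2D-3D replicate 3) and Efemp1 (-3.28 ± 0.51) were lower and Ltbp2 (4.03 ± 0.50) higher. Cell cycle genes fell in 30 of 40 cases and rose in 0 (31 and 1 adjusted over the list alone, camera adjusted p = 9.07e-10, and 0.419 with an estimated correlation). Ccnb2 was at -3.48 ± 0.35. All 30 ribosomal protein genes fell, the same adjusted over the list alone (camera adjusted p = 3.15e-09, and 0.419 with an estimated correlation). Rpl32 (-0.71 ± 0.09) was among them. Stress response genes fell in 17 of 30 cases and rose in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 0.000535, and 0.508 with an estimated correlation), with the serine and folate enzymes Phgdh (-2.80 ± 0.33) and Mthfd2 (-2.05 ± 0.37) lower. Resting fibroblast markers fell in 12 of 27 cases and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.000535, and 0.221 with an estimated correlation), including Tcf21 (-1.92 ± 0.32).

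Growth factors (13 lower and 8 higher of 34, 15 and 9 adjusted over the list alone, camera adjusted p = 0.00982, and 0.0664 with an estimated correlation) were lower as a list, with a median of -0.21 that became 0.02 under library totals. Epicardial and mesothelial markers fell in 7 of 13 cases and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.0138, and 0.137 with an estimated correlation). Cytokines rose in 14 of 32 cases and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.0196, and 0.580 with an estimated correlation). That call ended with library totals (adjusted p = 0.217), without 3D-2D-3D replicate 1 (0.0588) or 2 (0.0565) and with 3D-2D-3D replicate 3 alone (0.599). Ccl2 was at 1.59 ± 0.73, not called. In the panel, Timp1 rose (2.82 ± 0.43), while Postn (-0.44 ± 0.28) and Pdgfra (0.08 ± 0.20) were not called. Macrophage markers had a mean log2 CPM of 2.36 to 2.41 in 3D-2D-3D and 3.12 to 3.13 in 3D-2D-2D, with 0 of 21 called in either direction and Lyz2 at -1.22 ± 0.83. In 3D-2D-3D, libraries 1 and 2 held almost no Y-linked reads, and replicate 3 held these and Xist, as 3D-2D-2D did. Whether that replicate, with more gene counts, shared the preparation of 3D-2D-2D is not known. Arrangement and preparation thus cannot be told apart here, collagens included. A fit with replicate 3 alone assumed it varied like the other groups. Scaling by library totals moved the median of all genes to 0.22 and gave 4747 genes higher and 1893 lower.

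The fifth comparison repeated 3D against 2D in cultures labelled 5 days. The contractile genes were again low in 3D, with Acta2 at -4.42 ± 0.45 (19.1 against 409.6 CPM, adjusted p = 1.30e-07), Tagln at -5.09 ± 0.38, Myl9 at -4.63 ± 0.45 and Fhl2 at -4.77 ± 0.27. Among the largest rises were the glutathione transferase Gsta4 at 6.25 ± 0.49, Csf2rb, a cytokine receptor chain, at 6.02 ± 0.73 (and 6.93 without 2D-5days replicate 1) and the complement component C7 at 5.84 ± 0.78. Mmp2 was again higher (2.76 ± 0.24, 6617 against 977 CPM). In all, 4548 of 14036 genes changed, 2098 higher and 2450 lower in 3D-5days, and 2159 of them by at least 2-fold.

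Other large rises were in Pi16 (5.60 ± 0.81), Aldh1a3, an enzyme of retinoic acid synthesis (5.44 ± 0.75, and 6.68 without 2D-5days replicate 1), Tgfbi (4.83 ± 0.27) and the adenylate cyclase Adcy5 (4.78 ± 0.89). Large falls were in Cemip (-7.93 ± 0.36, from 3552 to 14.5 CPM), Sema3d (-6.45 ± 0.64), Scel (-6.41 ± 0.52), Bmp4 (-6.33 ± 0.39), the proteoglycan gene Ogn (-6.27 ± 0.64), Col12a1 (-5.83 ± 0.61) and Col8a1 (-5.78 ± 0.31). Contractile genes fell in 21 of 26 cases and rose in 0 (23 and 0 adjusted over the list alone, camera adjusted p = 1.15e-24). YAP and TAZ targets fell in 13 of 22 cases and rose in 3 (14 and 5 adjusted over the list alone, camera adjusted p = 1.32e-07). Ankrd1 was at -5.35 ± 0.54, Amotl2 at -4.56 ± 0.19, Ctgf at -4.13 ± 0.33 and Cyr61 at -3.95 ± 0.59. Cholesterol synthesis genes fell in 23 of 24 cases and rose in 0 (24 and 0 adjusted over the list alone, camera adjusted p = 1.78e-28). Idi1 (-3.83 ± 0.44) and Nsdhl (-3.36 ± 0.29) were among them. Growth factors fell in 20 of 34 cases and rose in 2 (20 and 5 adjusted over the list alone, camera adjusted p = 2.79e-08). Gdf6 was at -4.45 ± 0.17. Integrin and focal adhesion genes fell in 17 of 28 cases and rose in 3 (17 and 4 adjusted over the list alone, camera adjusted p = 7.52e-06). The collagen-binding Itga11 (-3.03 ± 0.48) was among them. Oxidative stress genes rose in 17 of 23 cases and fell in 3, the same adjusted over the list alone (camera adjusted p = 2.79e-08). The cystine transporter Slc7a11 (3.26 ± 0.53, and 3.95 without 2D-5days replicate 1) rose, as did Hmox1 (heme oxygenase, 2.67 ± 0.53). Genes of cell-cell adhesion fell in 10 of 22 cases and rose in 4, the same adjusted over the list alone (camera adjusted p = 0.0146). The adhesion molecule Ncam1 was at -2.74 ± 0.29. Epicardial markers fell in 5 of 13 cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.000671). These 8 lists kept their calls with an estimated correlation, at adjusted p-values from 0.000475 for growth factors to 0.0411 for cell-cell adhesion.

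The remaining called lists did not. Cell cycle genes fell in 29 of 40 cases and rose in 0 (32 and 0 adjusted over the list alone, camera adjusted p = 4.62e-10, and 0.329 with an estimated correlation). Cenpf was at -3.88 ± 0.67 and Top2a at -3.42 ± 0.58. Lysosomal genes rose in 24 of 32 cases and fell in 1 (27 and 2 adjusted over the list alone, camera adjusted p = 8.57e-09, and 0.127 with an estimated correlation). Ctsb was at 2.03 ± 0.36, Psap at 1.92 ± 0.35 and Ctsd at 1.37 ± 0.29. Macrophage markers, at a mean log2 CPM of 6.69, 5.18 and 5.26 in 3D-5days and 5.54, 3.61 and 3.68 in 2D-5days, rose in 5 of 21 cases and fell in 0 (2 and 0 adjusted over the list alone, camera adjusted p = 0.0224, and 0.767 with an estimated correlation). That list's call ended with library totals (adjusted p = 0.0909) and without 2D-5days replicate 2 (0.0879), 2D-5days replicate 3 (0.0864) or 3D-5days replicate 1 (0.142). Collagen chains fell in 10 of 20 cases and rose in 3 (12 and 3 adjusted over the list alone, camera adjusted p = 0.000185, and 0.186 with an estimated correlation). Collagen processing genes fell in 12 of 20 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 3.41e-06, and 0.233 with an estimated correlation). Matrix glycoproteins fell in 17 of 38 cases and rose in 5, the same adjusted over the list alone (camera adjusted p = 0.00231, and 0.344 with an estimated correlation). Prelp (-5.04 ± 0.35), Fmod (fibromodulin, -4.68 ± 0.35), Loxl3 (-2.39 ± 0.22) and Plod2 (-2.25 ± 0.33) fell.

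Endothelial markers rose in 13 of 19 cases and fell in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 0.00231, and 0.317 with an estimated correlation), such as the receptor gene Tie1 (4.69 ± 1.03, and 5.72 without 2D-5days replicate 2). Hypoxia and glycolysis genes rose in 13 of 35 cases and fell in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 0.0147, 0.708 with an estimated correlation and 0.0775 without 2D-5days replicate 1). Egln3, an oxygen sensor (2.38 ± 0.56), and Car12, a carbonic anhydrase (2.23 ± 0.31) were among them. TGF-beta pathway genes fell in 11 of 25 cases and rose in 7 (12 and 7 adjusted over the list alone, camera adjusted p = 0.0356, and 0.154 with an estimated correlation). The inhibitory Smad6 was at -3.44 ± 0.21 and Id1 at -2.48 ± 0.43. The list's call ended without 2D-5days replicate 1 (adjusted p = 0.112), 3D-5days replicate 2 (0.148) or 3D-5days replicate 3 (0.0873). Adipogenic genes rose in 8 of 13 cases and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.0356, and 0.233 with an estimated correlation). Plin2 (2.84 ± 0.23) was among them. The adipogenic list was not called with library totals (adjusted p = 0.0514), without 2D-5days replicate 1 (0.0803), 2 (0.0514) or 3 (0.0511), and without 3D-5days replicate 1 (0.0601). Matrix proteases (camera adjusted p = 0.0518), protease inhibitors (0.134) and cytokines (0.313) were called only with the replicate block, at adjusted p-values of 0.000116, 0.0180 and 0.0116.

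In the panel at 5 days, Lox (-3.96 ± 0.48), Fn1 (-1.38 ± 0.20), Tcf21 (-2.69 ± 0.33) and Mki67 (-3.18 ± 0.81, and -4.36 without 3D-5days replicate 1) fell and Postn rose (1.22 ± 0.29). Timp1 was called higher (1.26 ± 0.41), and its call ended without 2D-5days replicate 1 (1.08) or 3D-5days replicate 2 (1.16) or 3 (1.03). Col1a1 (-0.84 ± 0.33, adjusted p = 0.0549), Col3a1 (-0.06 ± 0.61), Pdgfra (0.03 ± 0.20) and Igf1 (1.26 ± 0.52, adjusted p = 0.0661) were not called. Replicates 2 and 3 alone called 3830 genes and replicate 1 alone, with 1 library per group and the spread taken from the other groups, 2070, with an r of 0.74 across genes, and 3637 of the 3830 (95.0%) had the same sign in replicate 1. With the replicate block 5265 genes were called. Scaling by library totals moved the median of all genes to 0.13 and gave 2912 genes higher and 1877 lower.

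**Figure D3:**
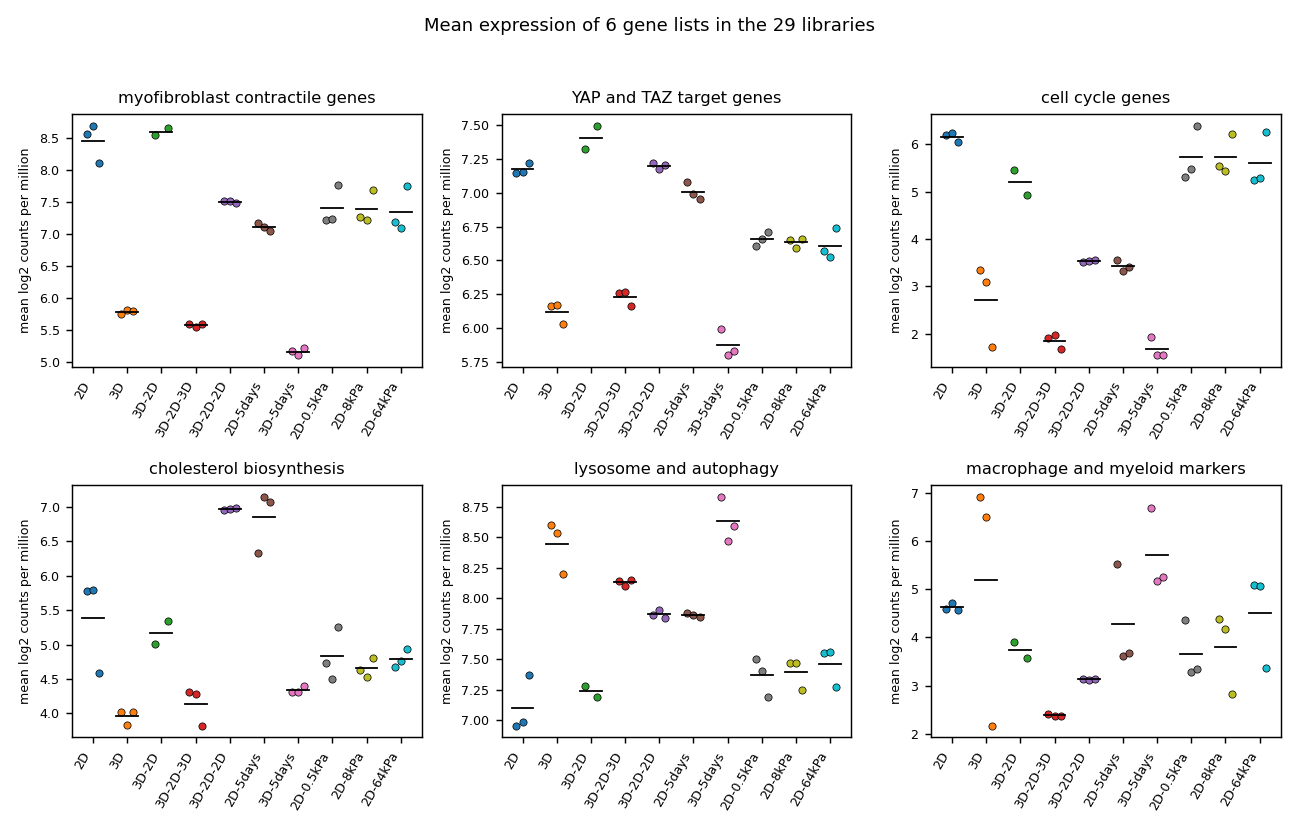
Mean log2 CPM of the members of 6 gene lists in the 29 libraries, with 1 point per library and a bar at the group mean. The macrophage mean was 6.94, 6.51 and 2.16 in the 3D libraries and 4.57 to 4.73 in the 2D libraries.

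The comparisons shared many genes. Calls that disagreed are not counted here. Of the genes called between 3D and 2D, 2890 were called in the same direction at 5 days. Of these 1359 rose and 1531 fell (560 and 669 if independent). The log2 fold changes had an r of 0.67 across genes, which are not independent replicates. With 3D-2D-3D against 3D-2D-2D 2584 were shared, 1128 higher and 1456 lower (742 and 790.0), with an r of 0.36. Of the genes called at 5 days 2612 were called in the opposite direction when 3D cells moved to 2D. By direction these were 1304 and 1308 (582 and 706), with an r of -0.52. Acta2, Tagln, Ctgf, Amotl2 and Ankrd1 fell in all 3 comparisons of 3D with 2D and rose on the move from 3D to 2D.

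The difference between 3D and 2D was tested for a change with culture time, as 5 days minus no stated time. It differed for 3583 genes, 1725 upward and 1858 downward. A lower 3D effect means a lower signed log2 fold change, so a fall that was larger at 5 days counts as lower. Prelp (-4.16 ± 0.44), Fmod (-4.61 ± 0.45) and Matn4 (-4.13 ± 0.35), all matrix proteins, and Tcf21 (-3.26 ± 0.46) and Smad6 (-3.65 ± 0.28) had a lower 3D effect at 5 days, while Gsta4 (4.12 ± 0.60), Psat1 (3.81 ± 0.26, adjusted p = 3.11e-09) and Timp1 (2.55 ± 0.58) moved the other way. Without 2D replicate 3 the difference was 1.82 for Timp1 and 3.52 for Gsta4, both still called. The contractile and YAP target genes Acta2 (1.43 ± 0.56, adjusted p = 0.0650) and Ctgf (-0.36 ± 0.41) and the collagen gene Col1a1 (-0.78 ± 0.46) were not called.

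The last comparisons asked whether the stiffness under a 2D layer changed expression, at 0.5, 8 and 64 kPa. Acta2 had mean CPM values of 664.6 (SD 381) at 0.5 kPa, 609 (SD 328) at 8 kPa and 626 (SD 387) at 64 kPa (n = 3 each). Between 0.5 and 64 kPa, Acta2 was at 0.09 ± 0.38, Tagln at 0.12 ± 0.31, Ctgf at -0.01 ± 0.29, Cyr61 at -0.02 ± 0.52, Col1a1 at -0.09 ± 0.33 and Lox at 0.12 ± 0.43. Acta2, Tagln, Ctgf and Col1a1 were at -0.04 ± 0.38, 0.05 ± 0.31, -0.06 ± 0.29 and -0.08 ± 0.33 between 8 and 64 kPa. Between 0.5 and 8 kPa they were at 0.13 ± 0.38, 0.07 ± 0.31, 0.05 ± 0.29 and -0.02 ± 0.33. No gene was called in the 3 comparisons by edgeR (175, 241 and 82 at an unadjusted p under 0.05) or DESeq2. With replicate numbers as a block, edgeR called 0 genes between 0.5 and 64 kPa, 608 between 8 and 64 kPa (214 higher and 394 lower at 8 kPa) and 2 between 0.5 and 8 kPa. In each pair more reads were not uniquely aligned at 8 (20.8% to 27.4%) than at 64 kPa (17.9% to 23.6%). This was not tested as a cause.

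With the block, the acute-phase gene Lcn2 (lipocalin) was higher at 8 than at 64 kPa (1.67 ± 0.06, adjusted p = 4.28e-08, higher in 3 of 3 pairs), as were the lubricin gene Prg4 (1.03 ± 0.12), the BMP antagonist Grem1 (0.91 ± 0.11), Mmp3 (0.64 ± 0.04, adjusted p = 3.02e-06), the chemokine genes Cxcl1 (0.51 ± 0.05) and Ccl2 (0.31 ± 0.06) and the arginase gene Arg1 (1.40 ± 0.15). The mannose receptor gene Mrc1 (-1.04 ± 0.07), the complement gene C1qa (-1.01 ± 0.14), Cd68 (-0.64 ± 0.06), Lyz2 (-0.76 ± 0.07), all of macrophages, and the collagen genes Col15a1 (-0.92 ± 0.07) and Col6a3 (-0.76 ± 0.08) were lower. These genes other than Mmp3, Ccl2 and Lyz2 were chosen after their values were seen. Of 17 macrophage markers tested in this blocked fit 16 fell and 0 rose, the same adjusted over the list alone, of 19 collagen chains 7 fell and 0 rose (10 and 1 adjusted over the list alone), and of 29 cytokines 8 rose and 2 fell (9 and 2 adjusted over the list alone). Without the block, oxidative stress genes were higher at 8 kPa as a list (median 0.23, camera adjusted p = 4.58e-09, and 0.0346 with an estimated correlation), with 0 of 23 members called over all genes and 2 higher adjusted over the list alone. With the block that list had an adjusted p = 4.56e-13, and 0.416 with an estimated correlation, where the lowest of any list was 0.256 between 8 and 64 kPa, 0.699 between 0.5 and 64 kPa and 0.659 between 0.5 and 8 kPa. Without the block, macrophage markers were lower as a list (median -0.81, camera adjusted p = 3.93e-07, and 0.893 with an estimated correlation), with 0 members called, and that call ended without 8 kPa replicate 3 (adjusted p = 0.105). At 0.5 against 64 kPa oxidative stress genes were higher (median 0.27, camera adjusted p = 8.67e-06, and 0.227 with an estimated correlation) and macrophage markers lower (median -0.90, camera adjusted p = 2.76e-11, and 0.950 with an estimated correlation), with 0 members of either called over all genes or adjusted over the list alone. At 0.5 against 8 kPa interferon genes were lower (median -0.63, camera adjusted p = 8.76e-10, and 0.883 with an estimated correlation), a call that ended without 0.5 kPa replicate 3 (adjusted p = 0.0873) and reversed without 8 kPa replicate 1 (0.557), and the blocked calls were Arg1 (-1.22 ± 0.10, adjusted p = 0.00290) and the ribosomal RNA gene Rn45s (-0.57 ± 0.06, adjusted p = 0.0111), both chosen after their values were seen.

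The other list calls between substrates in the fit without the block had 0 members called over all genes, and each ended or reversed without some single library. Leaving out 1 library also leaves its replicate number without a partner. Between 8 and 64 kPa, interferon genes were higher (median 0.60, camera adjusted p = 0.000458), a call that ended without 64 kPa replicate 3 (0.752) and reversed without 8 kPa replicate 1 (0.211). Cytokines were higher (median 0.24, camera adjusted p = 0.0259), which ended without 8 kPa replicate 1 (0.301) or 2 (0.312) and reversed without 64 kPa replicate 3 (0.994). Collagen chains were lower (median -0.10, camera adjusted p = 0.0105, with 1 member lower adjusted over the list alone), but not without 8 kPa replicate 3 (0.522) or 64 kPa replicate 1 (0.394). Collagen processing genes were lower (median -0.04, camera adjusted p = 0.0259), but not without 64 kPa replicate 1 (0.906) or 2 (0.354), and higher without 8 kPa replicate 3 (0.761). Cholesterol genes were lower (median -0.16, camera adjusted p = 0.0105), but not without 8 kPa replicate 2 (0.228) or 64 kPa replicate 3 (0.325). Resting markers were lower (median -0.11, camera adjusted p = 0.00240), but not without 8 kPa replicate 3 (0.439) or 64 kPa replicate 1 (0.139) or 2 (0.0870). Each of these 6 had an adjusted p = 0.893 with an estimated correlation. With the block, the 6 lists were called in the same directions, with members called over all genes. The adjusted p-values were 6.79e-09 for interferon genes (4 higher and 0 lower), 2.54e-06 for cytokines, 1.23e-08 for collagen chains, 0.00728 for collagen processing (0 and 3), 4.09e-05 for cholesterol genes (0 and 1) and 2.51e-07 for resting markers (0 and 9). With an estimated correlation in the blocked fit they were 0.256 for collagen chains, cytokines and resting markers, 0.416 for collagen processing and 0.476 for interferon and cholesterol genes. Between 0.5 and 8 kPa, cholesterol genes were higher (median 0.19, camera adjusted p = 1.25e-05, and 0.927 with an estimated correlation) and hypoxia genes lower (median -0.09, camera adjusted p = 0.0182, and 0.927 with an estimated correlation). The cholesterol call reversed without 0.5 kPa replicate 3 (0.813), and the hypoxia call without 0.5 kPa replicate 3 (0.0149), 8 kPa replicate 1 (0.432) or 8 kPa replicate 2 (0.9997). With the block the adjusted p-values were 8.69e-12 for cholesterol, 1.97e-09 for hypoxia and 3.98e-17 for interferon genes, with 0 members called over all genes, and each was 0.659 with an estimated correlation. Some lists were called only with the block. Cell cycle genes were higher at 0.5 kPa (camera adjusted p = 9.53e-10) and 8 kPa (4.03e-05) than at 64 kPa. Against 64 kPa, collagen chains were lower at 0.5 kPa (8.86e-05) and hypoxia genes higher at 8 kPa (0.000895). Oxidative stress genes were lower at 0.5 than at 8 kPa (6.21e-05). None of these was called with an estimated correlation.

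Shared calls between the softest substrate and 3D could not arise, since the substrate comparison called 0 genes. The log2 fold changes of 3D against 2D and of 0.5 against 64 kPa had an r of -0.10 across genes. It was -0.24 without 64 kPa replicate 3 and -0.23 without 0.5 kPa replicate 1, and turned to 0.07 without 0.5 kPa replicate 3, 0.03 without 64 kPa replicate 1 and 0.04 without 64 kPa replicate 2.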

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

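The sets of libraries by preparation were chosen after seeing the data, and the test of which splits kept the 2D libraries in their own times was chosen only after the result was seen. The effect of 3D differed between the cultures of 5 days and those of no stated time for 3583 of 14036 genes in a test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg adjustment, n = 3 libraries in each of 4 groups). Lower and higher give the sign of the difference, so a fall in 3D that was larger at 5 days counts as a lower effect. The matrix genes Fmod (-4.61 ± 0.45), Prelp (-4.16 ± 0.44) and Matn4 (-4.13 ± 0.35) had a lower effect at 5 days, as had the inhibitory signalling gene Smad6 (-3.65 ± 0.28) and the fibroblast transcription factor Tcf21 (-3.26 ± 0.46). The effect was higher for the glutathione transferase Gsta4 (4.12 ± 0.60), the serine synthesis gene Psat1 (3.81 ± 0.26) and the protease inhibitor Timp1 (2.55 ± 0.58). Without 2D replicate 3 Gsta4 was at 3.52 and Timp1 at 1.82.

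Among the gene lists, the effect was lower at 5 days for collagen chains (median difference -1.04, camera adjusted p = 6.04e-06, with 11 members lower and 1 higher), matrix glycoproteins (-0.87, adjusted p = 0.000552, 13 lower and 2 higher) and resting fibroblast markers (-0.98, adjusted p = 0.000897). It was also lower for cholesterol synthesis (-0.96, adjusted p = 2.22e-05), lysosomes (-0.64, adjusted p = 2.77e-07, 18 lower and 0 higher), growth factors (-0.70, adjusted p = 0.0293) and the TGF-beta pathway (-0.23, adjusted p = 0.0104). The fall of cholesterol genes in 3D was thus larger at 5 days, with a median of -2.72 against -1.60. From no stated time to 5 days the median of this list changed by 1.52 within 2D and by 0.34 within 3D. Those contrasts of times were chosen after the result was seen. The effect was higher for the cell cycle (1.55, adjusted p = 4.83e-11, 21 higher and 0 lower), ribosomal proteins (0.56, adjusted p = 7.98e-11, 24 higher and 0 lower), contractile genes (0.61, adjusted p = 0.000897) and oxidative stress (0.75, adjusted p = 0.00118). The falls of cell cycle and contractile genes in 3D were thus smaller at 5 days, with medians of -1.82 against -3.50 and -1.86 against -2.14. Higher values were also found for hypoxia and glycolysis (0.60, adjusted p = 0.00375), the unfolded protein and integrated stress responses (0.32, adjusted p = 7.84e-05) and endothelial markers (1.49, adjusted p = 0.0476, and 0.0676 with the replicate block). None of the 14 lists was called with an estimated correlation, with adjusted p-values from 0.252 for collagen chains to 0.545 for hypoxia. The endothelial call ended without 2D replicate 3 (adjusted p = 0.122), 3D replicate 3 (0.223), 2D-5days replicate 1 (0.104) or 3D-5days replicate 2 (0.102) or 3 (0.133). The TGF-beta call ended without 2D-5days replicate 1 (0.0555) and the growth factor call without 3D replicate 2 (0.0504). Matrix proteases (camera adjusted p = 0.0580), interferon genes (0.0827) and cardiomyocyte markers (0.197) were called lower only with the replicate block, at 0.0309, 0.0214 and 0.0457.

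Sequencing depth differed between the times, but with every library thinned to the lowest total 3222 genes were still called, which argues against depth as the cause. Preparation stays open. The effect of 3D differed between replicates 1 and 2 and replicate 3 of no stated time for 1904 genes, against 4631 between 5-day replicates 2 and 3 and that replicate 3, and 38 between the 5-day preparations, with each lone library assumed to vary like the other groups. Culture time and preparation cannot be told apart, since no preparation is known to have been used at both times. Of 200 ways to part the libraries into times within each arrangement, 100 were drawn, and 8 of these, the real one included, called as many genes. The 7 others all kept the 2D libraries in their own times. The 11 drawn splits that did so called 3276 to 6419 genes, and the 88 that moved 2D libraries between times at most 2571. Those 11 carry the difference between times within 2D, 6266 genes, so they do not show what chance gives, and whether chance can be excluded was not settled.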

How the results depend on the processing

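The settings that sum the most alike libraries, keep 1 inferred preparation or add the block to DESeq2, and the estimated correlation with the block, were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of those reported under RLE factors, library totals, both filters and DESeq2. Without each library in turn they were 6651 to 7340 for 3D with 2D, 5761 to 7845 for 3D-2D with 3D, 171 to 2947 for 3D-2D with 2D, 4702 to 5162 for 3D-2D-3D with 3D-2D-2D, 3652 to 4561 at 5 days, 2939 to 3886 for the difference between times, and 0 by edgeR for each substrate pair. The extremes of 3D-2D with 2D came without 3D-2D replicate 2 and 2D replicate 3. A lone remaining library was assumed to vary like the other groups.

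With only the groups compared, 3D-2D with 2D called 523 genes, 5 days 2991 and the difference between times 2156, with fewer libraries to estimate the spread. Summed libraries gave 220, 2512 and 1379. The block gave 6264 for 3D-2D with 2D, although its numbers do not pair those libraries, 608 between 8 and 64 kPa and 2 between 0.5 and 8 kPa. DESeq2 with the block gave 247, 2 and, between 0.5 and 64 kPa, 4. Replicate 3 of 3D-2D-3D alone gave 3469. At 2-fold or more, shared calls with 3D against 2D were 1360 at 5 days and 1125 for 3D-2D-3D, and 1220 were opposite between 5 days and the move from 3D to 2D. Beyond fewer libraries or a higher minimum, the cause was not tested.

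Lists called with an estimated correlation were 4 for 3D with 2D, 3 for 3D-2D with 3D, 0 for 3D-2D with 2D, 0 for 3D-2D-3D, 8 at 5 days, 0, 1 and 0 for 0.5 with 64, 8 with 64 and 0.5 with 8 kPa, and 0 for the difference between times, where 14, 12, 9, 13, 18, 2, 8, 3 and 14 were reported. With the block added, that 1 list, of oxidative stress, had an adjusted p = 0.416, and the lowest of any substrate list was 0.256. The test fry called 22 for 3D-2D with 3D, 3 for 3D-2D with 2D, 21 for 3D-2D-3D and 0, 0 and 0 for substrates. The block gave 20, 14, 9, 14 and 10 for 3D-2D with 3D, 3D-2D with 2D and the 3 substrate pairs, only the groups compared 8 and 5 for 0.5 with 64 and 0.5 with 8 kPa, and replicate 3 alone 7 for 3D with 2D. Without single libraries the substrate pairs called 3 to 13, 5 to 12 and 6 to 12 lists.

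Directions reversed for 6 list calls between substrates when 1 library was left out, and the cause was not tested. Between 8 and 64 kPa adjusted p-values ran from 9.73e-05 to 0.906 for collagen processing (0.761 where it reversed, without 8 kPa replicate 3), from 0.000174 to 0.994 for cytokines (reversed without 64 kPa replicate 3) and from 5.18e-09 to 0.752 for interferon genes (0.211 reversed, without 8 kPa replicate 1). Between 0.5 and 8 kPa they ran from 3.03e-14 to 0.9997 for hypoxia (reversed without 8 kPa replicate 2, at 0.0149 without 0.5 kPa replicate 3 and at 0.432 without 8 kPa replicate 1), from 1.13e-11 to 0.813 for cholesterol (reversed without 0.5 kPa replicate 3) and from 5.98e-15 to 0.557 for interferon genes (reversed without 8 kPa replicate 1).

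Over all settings, 1100 list results were unchanged in call and direction, 177 lost a call and 8 reversed. Of the named gene results 4573 were unchanged, 150 lost a call, 69 gained 1 and 1 reversed, Fn1 between 3D and 2D, at 0.19 in replicate 3 alone. A planted 1.5-fold change was recovered in 10.4% to 31.3% of genes in the 5 simulated comparisons.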

Other observations

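The contrasts of culture times and the tests of macrophage markers and lysosomal genes were chosen only after the result was seen. In 2D, 6266 genes differed between 5 days and no stated time, 3134 higher and 3132 lower (edgeR, n = 3 per group). Matn4 (5.31 ± 0.28), the neuropeptide precursor Scg2 (5.71 ± 0.54), Tcf21 (2.35 ± 0.33), Mmp2 (1.94 ± 0.24) and Col3a1 (1.72 ± 0.63) were higher at 5 days. Npnt (-5.34 ± 0.45), Ptgs2 (-3.97 ± 0.70), Mki67 (-3.42 ± 0.74), Tagln (-2.95 ± 0.33) and Acta2 (-2.90 ± 0.41) were lower. Of 26 contractile genes 22 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 5.85e-11, and 0.232 with an estimated correlation), and of 40 cell cycle genes 39 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 1.09e-26, and 0.232 with an estimated correlation). Cholesterol synthesis genes rose in 22 of 24 cases (23 adjusted over the list alone, camera adjusted p = 1.33e-10, and 0.411 with an estimated correlation). Lysosomal genes rose in 24 of 32 cases and fell in 0 (25 and 0 adjusted over the list alone, camera adjusted p = 4.49e-12, and 0.232 with an estimated correlation). Resting fibroblast markers rose in 16 of 27 and fell in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 5.58e-05, and 0.232 with an estimated correlation). Genes of the unfolded protein and integrated stress responses fell in 10 of 30 and rose in 0 (8 and 0 adjusted over the list alone, camera adjusted p = 0.00995, and 0.710 with an estimated correlation).

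In 3D, 1460 genes differed between the times, 634 higher and 826 lower at 5 days. The complement genes C7 (4.87 ± 0.71) and C4b (3.14 ± 0.62), Abi3bp (3.49 ± 0.71) and Mme (2.75 ± 0.33) were higher. The early response gene Fosb (-5.14 ± 0.96), Hspb7 (-3.77 ± 0.49), Col12a1 (-3.27 ± 0.55) and Fmod (-2.69 ± 0.33) were lower. Of the lists called there, 2 kept their calls with an estimated correlation. Oxidative stress genes rose in 8 of 23 cases (12 adjusted over the list alone, camera adjusted p = 1.05e-08, and 0.0258 with an estimated correlation), and TGF-beta pathway genes fell in 9 of 25 and rose in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 4.85e-05, and 0.0258 with an estimated correlation). Between 2D-5days and 3D-2D-2D, 32 genes differed, 8 higher and 24 lower, among them Col15a1 (-2.32 ± 0.29, adjusted p = 0.000360), Acaa2 (0.92 ± 0.11) and Gabre (1.40 ± 0.26), while Acta2 was at -1.09 ± 0.39 (adjusted p = 0.316).

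Macrophage markers were higher in 3D than in 2D in replicates 1 and 2, with 20 of 21 members higher and a median of 2.28, and not in replicate 3, where 21 of 21 were not higher and the median was -2.90. Lyz2 had 4522 and 3192 CPM in 3D replicates 1 and 2, 105 in 3D replicate 3 and 474 to 808 in 2D, and Ctss, which is also in the protease list, 1019 and 736 CPM, 21.6 CPM and 83.3 to 99.1 CPM. If the share of fibroblasts were lower in 3D, the markers of every other cell type would rise alike. The macrophage median lay 1.79 (SE 0.491) above that of mural cell and cardiomyocyte markers in replicates 1 and 2. The endothelial median there, 2.03, was close to the macrophage median of 2.28, so the values do not decide this. In replicate 3 the endothelial median was -1.18. Interferon genes had medians of 1.54 in replicates 1 and 2 and -1.16 in replicate 3, so the turn was not limited to macrophage markers. Macrophages in different shares in the cultures of different preparations may account for the pattern, but the markers that show it were the values that raised this explanation, so it stays open. No sort or gate that would remove macrophages is given in the sources used here.

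Lysosomal genes were higher in 3D in replicates 1 and 2 (median 1.52, SE 0.107) and in replicate 3 (median 0.80, SE 0.139, 31 of 32 members above 0), where macrophage markers were not. Replicate 3 is 1 library per group, and these standard errors are over list members, not libraries, so macrophage RNA as the whole cause stays open. With library totals alone the median was 1.43 (SE 0.0768). The TMM factors were 1.05 to 1.10 in 3D and 0.978 to 0.990 in 2D. Factors this near to 1 could move the median only a little, so the refit could hardly have come out otherwise. Their size argues against the scaling as the cause. Between 3D-2D-3D and 3D-2D-2D, where macrophage markers had mean log2 CPM values of 2.36 to 3.13, the lysosomal median was 0.28. There 11 of 32 members rose and 3 fell, and the list was not called (camera adjusted p = 0.0572, and 0.0129 with library totals). A higher level of lysosomal transcripts in fibroblasts held in 3D and RNA of macrophages may each account for the rise between 3D and 2D, and these were not told apart.

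By root mean square difference of log2 CPM, 3D replicate 3 lay nearer to the 3D-2D-3D libraries (0.625 to 0.714) than to 3D replicates 1 and 2 (1.07 and 0.972) or 3D-5days replicates 2 and 3 (0.940 and 0.967). Its distance was 0.627 to the mean of 3D-2D-3D and 1.01 to that of the other 3D libraries.

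Whether a softer substrate moves genes as 3D does was tested with the genes called between 8 and 64 kPa with the block. Of 12610 genes in both tests, 132 moved alike at 8 kPa and in 3D (171 if independent) and 206 oppositely (165). The result was negative, but the calls hold 16 falling macrophage markers, so it does not decide this for fibroblasts.

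Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. For 3D with 2D 1 of the 10 splits called as many genes, the real one with 7576, and the highest other called 408. For 3D-2D-3D with 3D-2D-2D it was 1, with 5677 and 0, and at 5 days 1, with 4548 and 529. For 0.5 with 64, 8 with 64 and 0.5 with 8 kPa all 10, 10 and 10 splits called as many as the real ones with 0, 0 and 0 genes, and the highest others called 14, 0 and 0.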
